A study of Homo sapiens with 9 samples.

How the data were processed

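Gene expression was measured in subcutaneous tumours that grew from the human hepatocellular carcinoma cell line PLC/PRF/5 in athymic nude mice. Each of 9 tumour RNA samples was hybridised to 1 human Clariom S array, a whole-transcript oligonucleotide array that summarises each gene in a probe set. Per the labels' protocols, total RNA was extracted with Trizol, its integrity was assessed by microelectrophoresis, and the labelled target was made with the WT PLUS kit. Per the labels, 3 tumours came from mice given vehicle, 3 from mice given metformin at 50 mg/kg/day together with sorafenib at 15 mg/kg/day, and 3 from mice given the same doses with sorafenib 6 h after metformin. The sample titles call the vehicle tumours untreated. The labels do not state outright that each array came from its own animal, so the p-values measure the spread between these 9 samples. Arms given a single drug are mentioned in the growth protocol and were not analysed here.

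Per the series' design text and the submitters' processing notes, the authors normalised the arrays with SST-RMA, a variant of the RMA method with a signal space transformation, and worked in Transcriptome Analysis Console 4.0.2. The deposited values are on a log2 scale with 1 value per probe set and array. That the base is 2 was read from the values, whose lowest was 2.64 and whose highest was 19.13. The genome build and annotation version behind the probe sets are not given in the sources used here, so no coordinates are printed. The signal space transformation stretches differences relative to plain RMA, so fold sizes depend on that choice. No detection calls came with the values, and the level of a dim gene may be mostly background. No scan date or batch was given in the sources used here. Mouse host cells were part of each tumour, and human probes can bind mouse transcripts of similar sequence, so the values are not purely those of the human cells.

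The table held 21448 probe sets. Of these, 17709 had 1 gene symbol in the platform annotation, 0 had several and 3739 were unnamed here. All 17709 were matched by gene identifier to the RefSeq annotation of GRCh38.p14, which was used for names only and changed 0 symbols. For the 20 genes with more than 1 probe set, the probe set with the highest mean over the 9 arrays stood for the gene, which left 17687 genes. No gene was filtered out. Genes among the 40% with the lowest mean, under a log2 value of 6.02, are called dim below. Array medians ran from 6.67 to 6.78, and the correlation between any pair of arrays lay between 0.986 and 0.994. At most 1.92% of the probe sets had equal values in a pair of arrays, so no array was a copy of another. The precision is limited by the 3 arrays in each group.

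Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with group as its only term was fitted to the log2 values of all 9 arrays, which left 6 residual degrees of freedom, and variances were moderated by empirical Bayes. The contrasts were concomitant minus vehicle, sequential minus vehicle and sequential minus concomitant, each two-sided, with a moderated F-test over the 3 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Values are given as the mean ± SD of 3 tumours, and differences as log2 values with their standard error (SE) or 95% interval from limma. Fold sizes are printed as ratios of the higher to the lower level.

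The design, the alternatives, the rule for named genes and 56 gene lists, among them markers of 10 mouse cell types that a tumour can hold, were chosen before the data were examined. The lists held 1193 genes, of which 1056 were measured, and all 56 had at least 5 measured members. Each list was tested against all other genes with limma's camera at its preset inter-gene correlation of 0.01, with adjustment over the 56 lists in each comparison. Camera with an estimated correlation and fry, a rotation test that asks whether a list's genes move on balance in 1 direction, were run as alternatives. Members were also adjusted over their list alone, with no adjustment over the 56 lists. Chance alone can therefore give a passing member in a share of about 0.05 of the lists. Such members numbered 2, 7 and 8 in the 3 comparisons, with a gene in several lists counted in each. List levels per tumour are the means of the members' log2 values after each gene was centred on its mean over the 9 arrays. With 3 tumours against 3, an exact permutation test of such a level cannot give a p below 0.10. Genes are named by a fixed rule. Called genes with non-overlapping groups came first, up to 10 in each direction, and where fewer than 5 passed, the genes of the smallest p in that direction were added up to 5. A small p favours groups that do not overlap, so non-overlap in genes picked this way adds no support. Their intervals are not adjusted for the choice. For each list discussed, 2 to 4 members were named by the same order. A fixed panel was named in every comparison, with 13 measured genes. CA9, also in the panel, has no named probe set here.

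Alternatives included an intensity trend with a robust prior, array weights, the replicate number as a block, quantile normalization, median centring, omission of the dim genes, fits on the groups compared only, other thresholds, and omission of each array in turn. A fit on all probe sets, named or not, was added after the data were seen. The fit was also tested on simulated data for the concomitant minus vehicle comparison, with 200 of 17687 genes changed in each of 10 draws. It recovered 4.63% of genes changed by a log2 value of 0.5, 81.0% at 1 and 99.6% at 2, and 7.23% of its calls were unchanged genes. Lists shifted by 0.3 were called in 90% of cases, and 0.2 unshifted lists per draw were called, in data simulated with independent genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.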

Results

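Clariom S arrays of 9 PLC/PRF/5 xenograft tumours were compared between vehicle, a concomitant schedule of metformin and sorafenib, and a sequential schedule in which sorafenib followed metformin by 6 h. Metformin is a biguanide used in type 2 diabetes that inhibits mitochondrial complex I and activates AMPK, and sorafenib is a multikinase inhibitor of RAF, VEGF receptors and PDGF receptors used in liver cancer. The series title names a drug-drug interaction, so the comparisons ask how each schedule differed from vehicle and how the schedules differed from each other. Without a single-drug group they cannot test an interaction or assign a difference to either drug. The time from the last dose to tumour collection is not given in the sources used here. A difference between the schedules therefore cannot be told apart from a difference in time since dosing. Each group had 3 tumours, and 17687 genes were tested. Albumin (ALB) averaged 18.22 ± 0.10 and alpha-fetoprotein (AFP) 17.62 ± 0.04 in vehicle tumours (log2, SD, n = 3), near the highest value of each array, 18.56 to 19.13, where probes can saturate and differences can be understated. The first principal component held 24.3% of the variance. Along it, concomitant tumour 2 lay at 37.0 and sequential tumour 2 at -21.7, with the other concomitant tumours at -16.1 and 12.8.

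No gene differed between the 3 groups by limma's moderated F-test, whose lowest adjusted p was 0.983, and 0 genes passed in each pairwise comparison. At an unadjusted p under 0.05 the F-test gave 767 genes, or 4.34%, where chance alone gives 884.35. The pairwise tests gave 882 genes for concomitant minus vehicle, 665 for sequential minus vehicle and 888 for sequential minus concomitant, against the same chance number. Genes whose 3 values in 1 group did not overlap the 3 in the other made up 9.23%, 8.57% and 9.05% of all genes in these comparisons, where chance gives 10%.

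**Figure D1:**
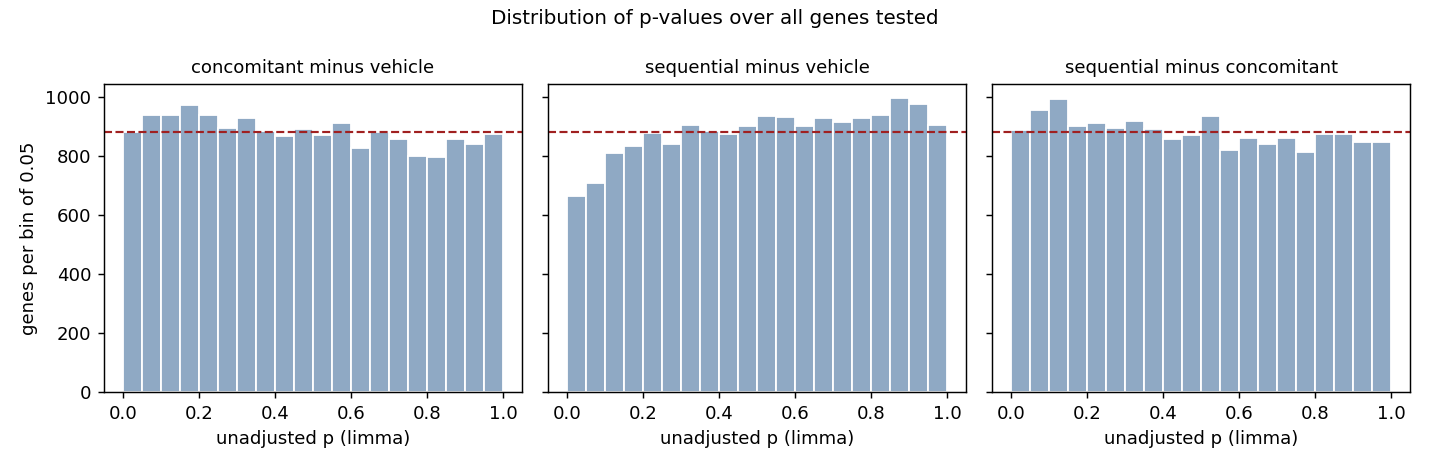
Number of genes (vertical axis) in each bin of width 0.05 of limma's unadjusted p (horizontal axis), 1 panel per comparison over 17687 genes, with the dashed line at the 884.35 genes per bin that chance gives. The lowest bins hold 882, 665 and 888 genes, none of them above the line by more than 4 genes.

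In tumours on the concomitant schedule, no gene passed the test against vehicle (limma, lowest adjusted p = 0.939). Among the genes nearest the threshold with higher values were CEACAM1, a cell adhesion glycoprotein, at 8.84 ± 0.82 against 6.85 ± 0.66 (log2, SD, n = 3), the fructose transporter SLC2A5 at 7.15 ± 0.97 against 5.57 ± 0.11, and ITIH4, a protein secreted by the liver, at 11.54 ± 0.75 against 10.12 ± 0.39. As groups, metallothioneins, endoplasmic reticulum chaperones, hypoxia response genes and immediate-early genes lay higher, and DNA replication genes and fibroblast markers lower, by camera at its preset correlation. None of these 6 lists passed when the correlation between genes was estimated from the arrays.

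Of the 882 genes at an unadjusted p under 0.05, 498 had higher and 384 lower values on the concomitant schedule, and 20 of the 882 differed at least 2-fold, 15 of them higher. ARMCX3, a protein of the mitochondrial outer membrane, differed by 0.96 (95% interval 0.60 to 1.32) and TMEM68 by 0.96 (0.56 to 1.36). CEACAM1 differed by 1.99 (1.01 to 2.96), SLC2A5 by 1.58 (0.78 to 2.38) and ITIH4 by 1.42 (0.70 to 2.15). The lower values nearest the threshold were those of the ubiquitin ligase TRIM31 at -0.97 (SE 0.20), the augmin subunit HAUS5 at -0.80 (SE 0.17), the aggrecanase ADAMTS4 at -0.72 (SE 0.17), the transcription factor KLF17 at -0.69 (SE 0.15) and the sorting protein PACS2 at -0.69 (SE 0.15). HAUS5, ADAMTS4 and KLF17 were dim. In these 10 genes the groups did not overlap, and each had an adjusted p of 0.939 by limma. Without concomitant tumour 3, whose SLC2A5 value of 6.03 lay below the 7.62 and 7.80 of the other concomitant tumours, SLC2A5 alone was called, with a log2 difference of 2.14 and a limma adjusted p of 0.0136.

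Metallothioneins, small metal-binding proteins, had higher values in 9 of 9 measured members, with a mean difference of 0.42 (camera adjusted p = 0.00341; adjusted p = 0.848 with an estimated correlation). MT1G differed by 0.52 (SE 0.22), MT1E by 0.38 (SE 0.14) and MT1X by 0.59 (SE 0.46). Members of this family are nearly identical in sequence, so which of them was measured is uncertain, and 0 passed when adjusted over the list alone. Endoplasmic reticulum chaperones had higher values in 15 of 19 members, with a mean difference of 0.17 (adjusted p = 0.0227; adjusted p = 0.848 with an estimated correlation). DNAJB9, a co-chaperone induced by unfolded proteins, averaged 11.94 ± 0.38 against 11.13 ± 0.09, and DNAJC3 12.91 ± 0.27 against 12.39 ± 0.23. Adjusted over the list alone, 1 chaperone passed, DNAJB9, and 0 passed over all genes.

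Hypoxia response genes had higher values in 18 of 22 members, with a mean difference of 0.23 (camera adjusted p = 0.0278; adjusted p = 0.848 with an estimated correlation). The secreted glycoprotein STC2 differed by 0.60 (SE 0.27), the sterol regulator INSIG2 by 0.59 (SE 0.23) and the angiogenic factor VEGFA by 0.18 (SE 0.18). Immediate-early genes, which respond to growth factors and stress within minutes, had higher values in 15 of 16 members, with a mean of 0.30 (adjusted p = 0.0290; adjusted p = 0.848 with an estimated correlation). Among them ATF3, a dim gene, differed by 0.62 (SE 0.22) and the MAP kinase phosphatase DUSP1 by 0.92 (SE 0.41). DNA replication genes had lower values in 28 of 35 members, with a mean of -0.16 (adjusted p = 0.00341; adjusted p = 0.865 with an estimated correlation). Their examples were E2F1 at -0.45 (SE 0.18) and the polymerase subunit POLE at -0.35 (SE 0.16). Adjusted over the list alone, 0 members of these 3 lists passed.

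Fibroblast and matrix markers, which in a xenograft are expected mainly in mouse stroma, had lower values in 12 of 16 members, with a mean of -0.35 and a median of -0.19 (camera adjusted p = 0.0185; adjusted p = 0.848 with an estimated correlation). Of the 16 members 11 were dim. Type I collagen COL1A1, which was dim, averaged 5.35 ± 0.43 against 6.39 ± 0.59 and was the 1 member that passed when adjusted over the list alone. The dim fibroblast protease FAP averaged 3.85 ± 0.14 against 4.46 ± 0.54. Markers of the other 9 host cell types did not pass. Their mean differences ranged from -0.11 for pericytes (adjusted p = 0.407) to 0.21 for erythroid cells (adjusted p = 0.898) and included 0.19 for macrophages (adjusted p = 0.211), 0.15 for neutrophils (adjusted p = 0.211) and 0.04 for endothelial cells (adjusted p = 0.898, limma's camera throughout).

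In the panel, the ERK-induced phosphatase DUSP6 averaged 9.40 ± 0.83 on the concomitant schedule and 8.59 ± 0.52 in vehicle tumours, and the RAS pathway inhibitor SPRY4 6.52 ± 1.03 and 5.85 ± 0.31. Differences in the glucose-responsive TXNIP (0.34), the stress gene DDIT3 (0.19), asparagine synthetase ASNS (0.28), cyclin D1 gene CCND1 (0.16), the proliferation marker MKI67 (-0.28), ALB (-0.10) and AFP (-0.11) had 95% intervals that included 0, as had those of the efflux pumps ABCB1 (-0.17, dim) and ABCG2 (-0.18). By fry, 0 lists passed and 2 had an unadjusted p under 0.05. Tumours of both groups lay apart in 7 of 56 lists, where chance gives 10%, and in 0 of the 6 called.

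Each of the 6 list calls was lost without at least 1 of the tumours. The adjusted p of camera is given for each loss, with the mean difference that remained. Without vehicle tumour 1 it was 0.428 for chaperones (mean 0.09), 0.243 for hypoxia (mean 0.17), 0.234 for fibroblast markers (mean -0.17) and 0.204 for immediate-early genes (mean 0.24). Without vehicle tumour 2 it was 0.475 for immediate-early genes (mean 0.11) and 0.0870 for each of hypoxia (mean 0.21), metallothioneins (mean 0.25) and DNA replication (mean -0.10). Without concomitant tumour 1 it was 0.0505 for hypoxia (mean 0.26), 0.153 for fibroblast markers (mean -0.28), 0.288 for metallothioneins (mean 0.17) and 0.999 for DNA replication, whose mean turned to 0.03. Without concomitant tumour 2 it was 0.154 for hypoxia (mean 0.16) and 0.198 for chaperones (mean 0.10), and without concomitant tumour 3 it was 0.104 for fibroblast markers (mean -0.27) and 0.280 for immediate-early genes (mean 0.17). For hypoxia these means ran from 0.16 to 0.26 against 0.23 over all tumours, so its lost calls did not show that the difference depended on a single tumour, nor did those of fibroblast markers without concomitant tumour 1 or 3 and of immediate-early genes without vehicle tumour 1. Calls were kept but means moved for DNA replication, to -0.25 without vehicle tumour 1 and -0.33 without concomitant tumour 3, and for immediate-early genes, to 0.55 without vehicle tumour 3. Quantile normalization ended the call of chaperones (0.0550), and without the dim genes the call of fibroblast markers ended (0.546).

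On the sequential schedule, no gene passed the test against vehicle either (limma, lowest adjusted p = 0.756). The measured differences included higher values of ITIH4, at 11.90 ± 0.43 against 10.12 ± 0.39 (log2, SD, n = 3), and of the metalloproteinase inhibitor TIMP3, at 10.11 ± 0.13 against 9.20 ± 0.22, and lower values of the RNA-binding protein RBMS2, at 7.98 ± 0.35 against 9.13 ± 0.26, and of haem oxygenase HMOX1, at 6.70 ± 0.54 against 8.17 ± 0.13. By camera at its preset correlation, gluconeogenesis genes and hepatocyte secreted proteins lay higher as groups. Glutathione and NRF2 target genes, NF-kB targets, hypoxia response genes, ERK output genes and fibroblast markers lay lower. With an estimated correlation, 0 of these 7 lists passed.

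The 665 genes at an unadjusted p under 0.05 were 341 with higher and 324 with lower values, and 19 of them differed at least 2-fold, 11 of those higher. ITIH4 differed by 1.78 (SE 0.33), TIMP3 by 0.91 (SE 0.17) and RBMS2 by -1.14 (SE 0.20), with a limma adjusted p of 0.756 for each. Other genes with higher values were CPB2, an inhibitor of fibrinolysis made in the liver, by 0.95 (SE 0.22), CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, by 0.78 (SE 0.18), and the histone gene H4C16, dim and nearly identical to other histone H4 genes, by 0.73 (SE 0.16). Lower values were found for COL1A1 at -1.26 (SE 0.27), the dim ADAMTS4 at -0.87 (SE 0.17), the GTPase-activating protein SRGAP1 at -0.86 (SE 0.17) and SH2D4A at -0.71 (SE 0.16). The groups did not overlap in any of these 10 genes.

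Glutathione and NRF2 target genes, which handle oxidative stress, had lower values in 19 of 22 members, with a mean of -0.26 (camera adjusted p = 0.000293; adjusted p = 0.179 with an estimated correlation). HMOX1 differed by -1.46 (SE 0.35) and the malic enzyme gene ME1, at 9.09 ± 0.09 against 9.65 ± 0.17, by -0.56 (SE 0.17). NF-kB and inflammatory targets had lower values in 14 of 21 members, with a mean of -0.23 (adjusted p = 0.000646; adjusted p = 0.179 with an estimated correlation). The chemokine CCL20 averaged 12.18 ± 0.22 against 13.25 ± 0.60, and NFKB2 9.44 ± 0.13 against 10.10 ± 0.11. Adjusted over the list alone, HMOX1 passed in the first list and CCL20 and NFKB2 in the second. Over all genes each of them had a limma adjusted p of 0.997. The 3 tumours of each group lay apart in both lists, for an exact two-sided permutation p of 0.10, the smallest that 3 against 3 can give. These calls held in all 9 fits without 1 tumour, with highest camera adjusted p of 0.00582 and 0.0181 at the preset correlation. Fits without a concomitant tumour could not change these differences, only the estimate of spread.

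Gluconeogenesis genes had higher values in 10 of 10 members, with a mean of 0.41 (camera adjusted p = 0.000293; adjusted p = 0.689 with an estimated correlation), among them the glucose-6-phosphate transporter SLC37A4 by 0.47 (SE 0.22) and pyruvate carboxylase PC by 0.54 (SE 0.25). Hepatocyte secreted proteins had higher values in 24 of 27 members, with a mean of 0.22 (adjusted p = 0.00176; adjusted p = 0.689 with an estimated correlation), among them antithrombin SERPINC1 by 0.76 (SE 0.33) and the apolipoprotein APOA2 by 0.31 (SE 0.16). Hypoxia response genes had lower values in 20 of 22 members, with a mean of -0.21 (adjusted p = 0.00268; adjusted p = 0.689 with an estimated correlation). The matrix enzyme LOX differed by -0.71 (SE 0.29), ANKRD37 by -0.37 (SE 0.20) and VEGFA by -0.10 (SE 0.18). ERK output genes had lower values in 15 of 18 members, with a mean of -0.20 (adjusted p = 0.00993; adjusted p = 0.689 with an estimated correlation). Here the phosphatase DUSP5 differed by -0.49 (SE 0.21), the inhibitor SPRED1 by -0.44 (SE 0.24) and DUSP6 by -0.16 (SE 0.35). Adjusted over the list alone, 0 members of these 4 lists passed.

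Fibroblast and matrix markers had lower values in 12 of 16 members, with a mean of -0.36 and a median of -0.19 (camera adjusted p = 0.00414; adjusted p = 0.689 with an estimated correlation). COL1A1 averaged 5.13 ± 0.09 against 6.39 ± 0.59 and passed when adjusted over the list alone, and COL1A2 averaged 9.38 ± 0.61 against 10.80 ± 1.41. Of the other host cell lists, pericyte markers averaged -0.17 (adjusted p = 0.147), endothelial markers -0.03 (adjusted p = 0.526), macrophage markers 0.07 (adjusted p = 0.526), erythroid markers -0.04 (adjusted p = 0.169) and skeletal muscle markers -0.09 (adjusted p = 0.240, limma's camera). In lists that were not called, 1 member passed when adjusted over the list alone in each of 3 cases, which were chosen after their values were seen. They were HMOX1 among ferroptosis genes, CYP1A1 among drug-metabolising enzymes and the haemoglobin gene HBB, at 7.38 ± 0.09 against 8.34 ± 0.45, among erythroid markers. Haemoglobin genes resemble each other and their mouse counterparts, so the source of this signal is uncertain.

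All 13 measured panel genes, DUSP6 and VEGFA among them, had intervals that included 0. DDIT3 averaged 6.63 ± 0.20 against 7.10 ± 0.18, ASNS 10.24 ± 0.33 against 10.60 ± 0.26 and AFP 17.78 ± 0.10 against 17.62 ± 0.04. Differences were 0.27 for SPRY4, 0.24 for TXNIP, -0.05 for MT1X, -0.14 for CCND1, -0.20 for MKI67, 0.04 for ALB, 0.15 for ABCG2 and -0.11 for the dim ABCB1. By fry, 0 lists passed and 3 had an unadjusted p under 0.05, and tumours lay apart in 4 of 56 lists, where chance gives 10%. Camera's call was lost without vehicle tumour 1 for fibroblast markers (adjusted p = 0.171, mean -0.19), gluconeogenesis (0.0905, mean 0.20) and hepatocyte secreted proteins (0.0956, mean 0.16), without vehicle tumour 2 for ERK output (0.114, mean -0.14), and without vehicle tumour 3 for hypoxia (0.225, mean -0.13). Without sequential tumour 2 it was lost for ERK output (0.460, mean -0.08) and hypoxia (0.684, mean -0.04). The means of ERK output without vehicle tumour 2 and of hepatocyte secreted proteins without vehicle tumour 1 stayed nearer those over all tumours, -0.20 and 0.22, so these losses did not show dependence on that tumour. Calls were kept but means moved for gluconeogenesis, to 0.64 without vehicle tumour 3, and for hypoxia, to -0.33 without sequential tumour 3.

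Between the schedules, no gene passed the test (limma, lowest adjusted p = 0.533). The gene nearest to the threshold was CCL20, a chemokine that attracts CCR6-bearing leukocytes, at 12.18 ± 0.22 on the sequential and 13.88 ± 0.33 on the concomitant schedule (log2, SD, n = 3), with vehicle tumours at 13.25 ± 0.60. As groups, hypoxia response genes, ERK output genes, ATF4 targets, immediate-early genes, heat shock proteins, metallothioneins and NF-kB targets lay lower on the sequential schedule by camera at its preset correlation. DNA replication genes, TCA cycle enzymes and drug transporters lay higher. With an estimated correlation, 0 of these 10 lists passed.

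Of the 888 genes at an unadjusted p under 0.05, 388 had higher and 500 lower values on the sequential schedule, and 14 of them differed at least 2-fold, 12 of those lower. CCL20 differed by -1.71 (95% interval -2.29 to -1.12). The other lower values were those of DNAJB9 at -0.90 (SE 0.20), ARMCX3 at -0.82 (SE 0.17), TMEM68 at -0.82 (SE 0.19) and the sarcoglycan SGCE at -0.71 (SE 0.16). Higher values were found for the keratin KRT76 by 0.73 (SE 0.17), CYP1A1 by 0.70 (SE 0.18), the tRNA-modifying enzyme DUS2 by 0.64 (SE 0.16), TRIM45 by 0.64 (SE 0.16) and the mitochondrial tRNA ligase FARS2 by 0.60 (SE 0.16). The groups did not overlap in any of these 10 genes, and each gene except CCL20 had a limma adjusted p of 0.933. Without concomitant tumour 3, SLC2A5 was called here too, at a log2 difference of -2.00 and a limma adjusted p of 0.0274, against -1.44 with all tumours.

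Hypoxia response genes had lower values on the sequential schedule in 20 of 22 members, with a mean of -0.44 (camera adjusted p = 7.06e-08; adjusted p = 0.594 with an estimated correlation). At the preset correlation this list was called in all 3 comparisons, at 0.23 above vehicle on the concomitant and -0.21 on the sequential schedule. With an estimated correlation it did not pass in any of them, and both calls against vehicle were lost without certain single tumours. LOX averaged 6.93 ± 0.53 against 8.02 ± 0.49, INSIG2 10.07 ± 0.49 against 10.91 ± 0.24, STC2 8.84 ± 0.48 against 9.72 ± 0.36 and VEGFA 12.91 ± 0.15 against 13.18 ± 0.27. Adjusted over the list alone, LOX, INSIG2 and STC2 passed, while 0 passed over all genes. ERK output genes had lower values in 18 of 18 members, with a mean of -0.45 (adjusted p = 1.85e-06; adjusted p = 0.594 with an estimated correlation). DUSP5 differed by -0.69 (SE 0.21), SPRY1 by -0.60 (SE 0.20), DUSP6 by -0.96 (SE 0.35), SPRY4 by -0.40 (SE 0.37) and CCND1 by -0.31 (SE 0.31). The count adjusted over the list alone was 0. The concomitant tumours were spread widely on this list, at -0.33, 0.66 and 0.37, around sequential values of -0.12, -0.45 and -0.08.

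**Figure D2:**
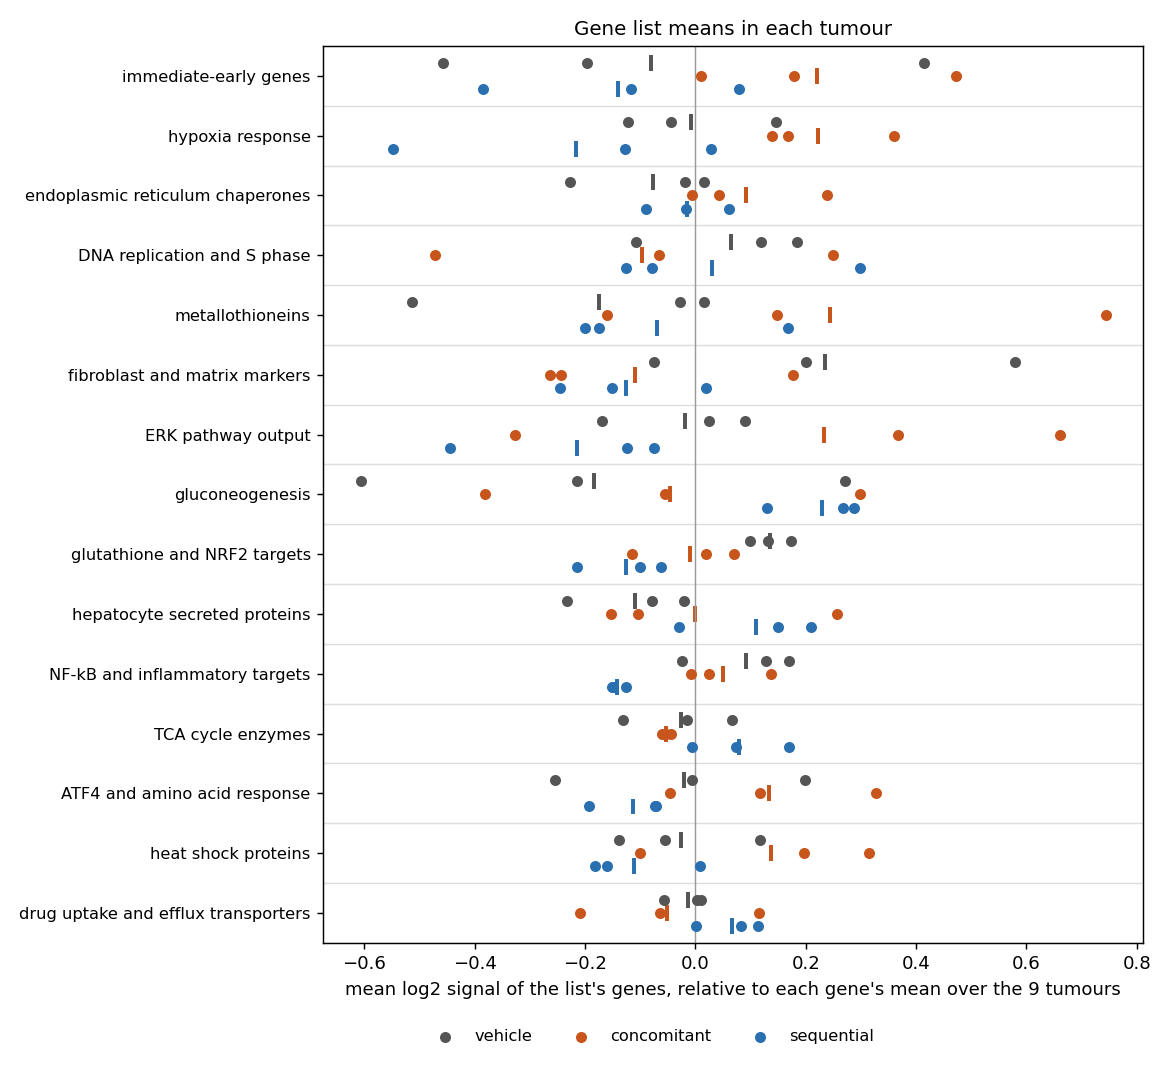
Mean centred log2 value per tumour (horizontal axis) for the 15 gene lists called in any comparison, with 1 dot per tumour, 3 per group, and a vertical bar at each group mean. On the hypoxia response list the concomitant tumours lie between 0.14 and 0.36, the sequential tumours between -0.55 and 0.03 and the vehicle tumours between -0.12 and 0.15.

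ATF4 and amino acid response genes, the transcriptional arm of the integrated stress response, had lower values in 26 of 32 members, with a mean of -0.25 (camera adjusted p = 0.000165; adjusted p = 0.594 with an estimated correlation). The folate enzyme MTHFD2 averaged 10.81 ± 0.07 against 11.61 ± 0.56, ASNS differed by -0.63 (SE 0.21) and DDIT3 by -0.65 (SE 0.23), and STC2 belongs to this list as well as to the hypoxia list. Heat shock proteins had lower values in 9 of 12 members, with a mean of -0.25 (adjusted p = 0.00803; adjusted p = 0.594 with an estimated correlation). HSPA1A, which has a near-identical copy and is therefore uncertain, differed by -0.57 (SE 0.15) and passed when adjusted over the list alone, and DNAJB1 differed by -0.57 (SE 0.20). Immediate-early genes had lower values in 13 of 16 members, with a mean of -0.36 (adjusted p = 0.00379; adjusted p = 0.594 with an estimated correlation), among them DUSP1 at -1.08 (SE 0.41) and KLF6 at -0.90 (SE 0.33). Metallothioneins had lower values in 9 of 9 members, with a mean of -0.31 (adjusted p = 0.0128; adjusted p = 0.594 with an estimated correlation), among them MT1X at -0.64 (SE 0.46), MT1G at -0.41 (SE 0.22) and MT1E at -0.40 (SE 0.14). NF-kB targets had lower values in 15 of 21 members, with a mean of -0.19 (adjusted p = 0.0394; adjusted p = 0.594 with an estimated correlation), and CCL20 passed when adjusted over the list alone, while NFKB2 differed by -0.36 (SE 0.17). The count adjusted over the list alone was 0 for the ATF4, immediate-early and metallothionein lists.

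TCA cycle enzymes had higher values on the sequential schedule in 15 of 18 members, with a mean of 0.13 (camera adjusted p = 0.0223; adjusted p = 0.594 with an estimated correlation), among them citrate synthase CS by 0.36 (SE 0.16) and PDHB by 0.35 (SE 0.17). DNA replication genes had higher values in 26 of 35 members, with a mean of 0.13 (adjusted p = 0.0164; adjusted p = 0.797 with an estimated correlation), among them POLE by 0.50 (SE 0.16) and POLA2 by 0.82 (SE 0.29). Drug uptake and efflux transporters, of which 9 of 20 were dim, had higher values in 15 members, with a mean of 0.12 (adjusted p = 0.0391; adjusted p = 0.594 with an estimated correlation), among them ABCC10 by 0.41 (SE 0.18), ABCG2 by 0.33 (SE 0.20) and the dim ABCB1 by 0.06 (SE 0.16). Adjusted over the list alone, 0 members of these 3 lists passed. The remaining panel differences were -0.10 for TXNIP, 0.09 for MKI67, 0.14 for ALB and 0.28 for AFP, with intervals that included 0.

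No host cell list passed between the schedules. Fibroblast markers averaged -0.02 (camera adjusted p = 0.923), with LOX, a member of this list too, passing when adjusted over the list alone. Erythroid markers averaged -0.25 (adjusted p = 0.157), macrophage markers -0.13 (adjusted p = 0.472), endothelial markers -0.07 (adjusted p = 0.600), keratinocyte markers -0.14 (adjusted p = 0.166) and adipocyte markers -0.11 (adjusted p = 0.379). Tumours lay apart in 8 of 56 lists, where chance gives 10%. Of the 10 called lists, 4 were among them, namely hypoxia, TCA cycle, ATF4 and NF-kB, each with an exact two-sided permutation p of 0.10, the smallest possible. By fry, 0 lists passed and 4 had an unadjusted p under 0.05. In lists that were not called, DNAJB9 among chaperones and CYP1A1 among drug-metabolising enzymes passed when adjusted over the list alone.

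At the preset correlation only, the calls of hypoxia, ERK output and ATF4 lists held in all 9 fits without 1 tumour, with highest camera adjusted p of 0.00288, 0.0172 and 0.0235. Fits without a vehicle tumour could not change the differences between schedules, only the estimate of spread. Over all tumours the 3 lists had an adjusted p of 0.594 with an estimated correlation and 0.565 by fry, and their size rested in part on single tumours. The mean difference of the hypoxia list went from -0.44 to -0.27 without sequential tumour 2, that of the ERK list from -0.45 to -0.24 without concomitant tumour 2 and to -0.73 without concomitant tumour 1, and that of the ATF4 list from -0.25 to -0.15 without concomitant tumour 2.

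The other 7 calls were lost without at least 1 tumour, with the mean that remained in parentheses. Without sequential tumour 1 the adjusted p by camera was 0.0517 for both NF-kB (mean -0.19) and heat shock (mean -0.21) and 0.0794 for transporters (mean 0.11). Without sequential tumour 2 it was 0.744 for DNA replication (mean -0.01), 0.179 for the TCA cycle (mean 0.09), 0.132 for transporters (mean 0.09), 0.123 for immediate-early genes (mean -0.24), 0.0841 for metallothioneins (mean -0.26) and 0.0831 for NF-kB (mean -0.20). Without sequential tumour 3 it was 0.0803 for both metallothioneins (mean -0.25) and NF-kB (mean -0.19). Without concomitant tumour 1 it was 0.653 for DNA replication, whose mean turned to -0.06, 0.637 for metallothioneins (mean -0.06), 0.248 for NF-kB (mean -0.15) and 0.101 for the TCA cycle (mean 0.13). Without concomitant tumour 2 it was 0.389 for transporters (mean 0.04) and 0.0820 for heat shock (mean -0.16), and without concomitant tumour 3 it was 0.0628 for heat shock (mean -0.22), 0.0769 for transporters (mean 0.11) and 0.103 for immediate-early genes (mean -0.23). The NF-kB mean over all tumours was -0.19, so its lost calls did not show that the difference depended on a single tumour, nor did those of heat shock without sequential tumour 1 or concomitant tumour 3, transporters without sequential tumour 1 or 2 or concomitant tumour 3, metallothioneins without sequential tumour 2 or 3, and the TCA cycle without concomitant tumour 1. Calls were kept but means moved for DNA replication, to 0.21 without sequential tumour 1 and 0.30 without concomitant tumour 3, for transporters, to 0.20 without concomitant tumour 1, and for metallothioneins, to -0.52 without concomitant tumour 2. Without the dim genes the call of transporters ended (0.0675).

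**Figure D3:**
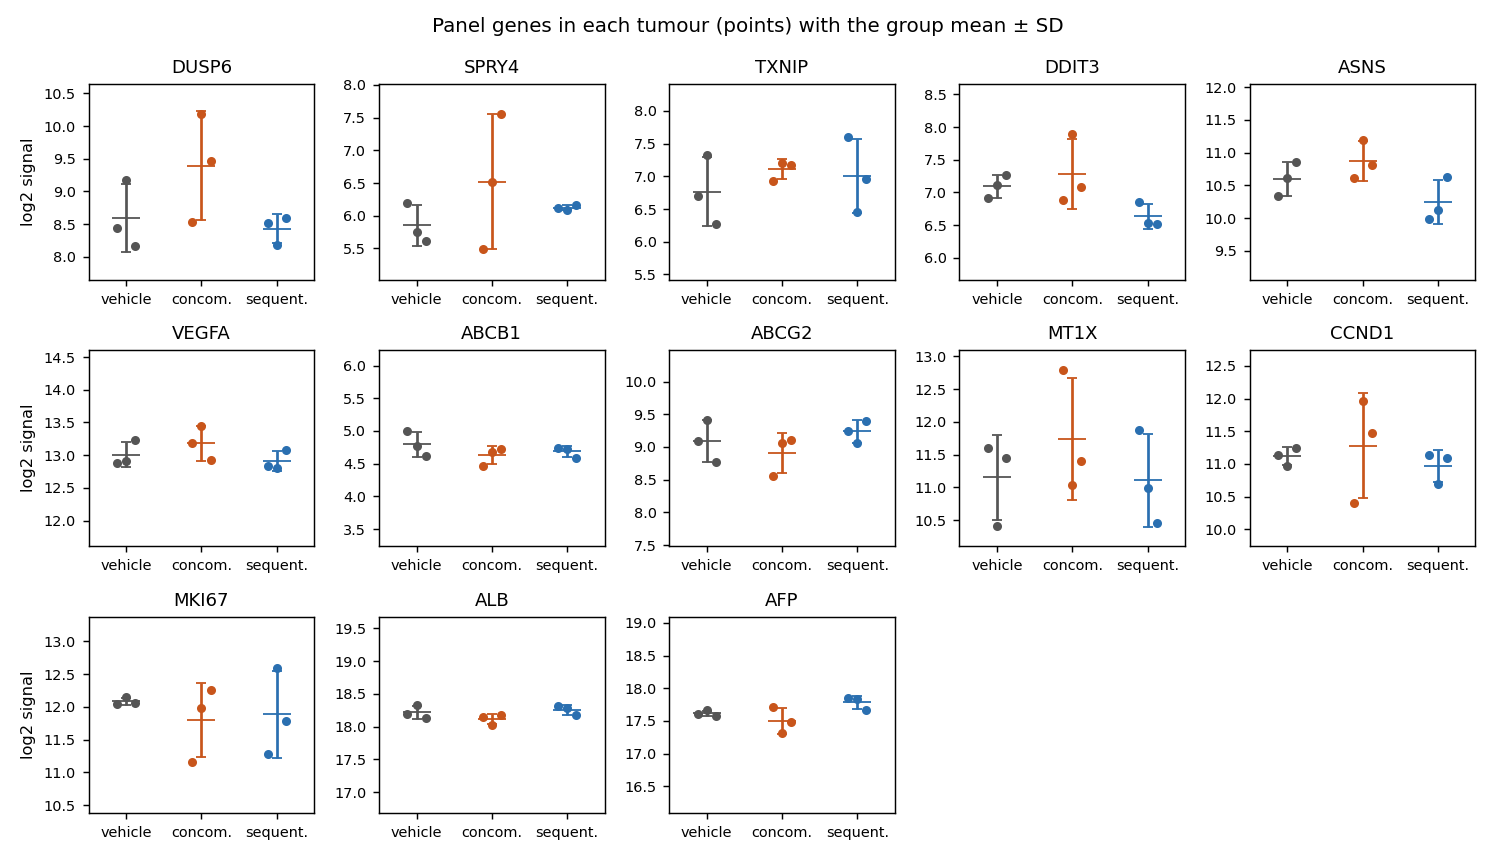
Log2 values of the 13 measured panel genes (vertical axes, each spanning 3 log2 units) in vehicle, concomitant and sequential tumours, with 1 point per tumour and the group mean ± SD (n = 3). DUSP6 averages 9.40 ± 0.83 on the concomitant schedule against 8.59 ± 0.52 and 8.43 ± 0.22 in the vehicle and sequential groups, and no panel gene passed the test.

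The log2 differences of both schedules against vehicle were compared across the 17687 genes. ITIH4 (1.42 on the concomitant and 1.78 on the sequential schedule), TIMP3 (0.67 and 0.91), COL1A1 (-1.04 and -1.26) and HMOX1 (-1.02 and -1.46) differed from vehicle in the same direction on both, none of them past the adjusted threshold. The Pearson correlation across genes was 0.463, with a covariance of 0.0210. Genes are not independent replicates, and both comparisons share the 3 vehicle tumours. In 100 data sets simulated without any group effect, with the arrays' own gene-gene covariance, the median correlation was 0.603, with the central 95% between -0.410 and 0.928, and the median covariance 0.0212, with the central 95% between -0.0138 and 0.0661. At an unadjusted p under 0.05, 79 genes were higher and 80 lower on both schedules, where independent lists would share 9.60 and 7.03 genes and the simulated data shared a median of 4.5 in each direction, with the central 95% reaching up to 773 and 858. The vehicle group was too small to split. The correlation and covariance lay below their simulated medians, so they showed no similarity beyond what shared vehicle tumours give without any effect. The overlap lay above the simulated median but below the upper limit. That range was too wide to decide how much of the overlap comes from the shared controls.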

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

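The fits without 1 tumour were planned as alternatives, but every test below was chosen for this list after its difference had been seen, those with other splits of the tumours and simulated data before their own outcomes were seen. The hypoxia response list drew attention because its difference between the schedules passed camera at the preset correlation, at a mean log2 value of -0.44 (sequential minus concomitant; adjusted p = 0.594 with an estimated correlation), while it lay on opposite sides of vehicle on the schedules. Reliance of the call on 1 tumour is argued against, since the highest adjusted camera p at the preset correlation without 1 tumour was 0.00288, but its size is not independent of sequential tumour 2, without which the mean was -0.27, and the lower level of sequential than of vehicle tumours did rest on that tumour, with an adjusted p of 0.684 without it. Selection of the most extreme of 56 lists in 3 comparisons could account for it, since 86 of 100 splits of the 9 tumours into 3 groups of 3 gave a camera p as small somewhere (real 1.26e-09, smallest other 3.58e-67). Variation between tumours that the list's genes share cannot be told apart from an effect of the schedule: 1 of 100 simulated data sets without group effects had a mean difference as large in size, but that bound was too narrow because the simulation took a spread estimated on 6 degrees of freedom as known, and fry, which allows for this, gave an unadjusted p of 0.0374 and an adjusted p of 0.565. An effect of the schedule itself stays open and was not tested beyond this.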

How the results depend on the processing

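The fit on all probe sets was chosen after the data were seen, and the other alternatives were planned. Of 132 alternative values of the main counts and of the correlation between schedules, 107 stayed within the limits set for an equal result, 18 were larger, 7 smaller and 0 reversed. The larger values include the counts at an unadjusted p under 0.05, a looser threshold set against 0 called genes. For the correlation the limit was 0.261, an error estimated from the same fits without 1 tumour, so those fits could hardly exceed it. Called genes stayed at 0 in every comparison (limma) under the trend and robust prior, array weights, both normalizations, omission of dim genes, fits on the groups compared and all probe sets. At an unadjusted p under 0.05 there were 882, 665 and 888 genes in the concomitant minus vehicle, sequential minus vehicle and sequential minus concomitant comparisons, 20, 19 and 14 with at least a 2-fold difference, 767 by the moderated F-test and 715 by the unmoderated F-test. Called lists went from 6, 7 and 10 to 0, 0 and 0 both with an estimated correlation and with fry, and to 12 for concomitant minus vehicle without dim genes, where fewer genes were tested. Without 1 tumour, called genes ranged from 0 to 1, 0 to 0 and 0 to 1, and from 0 to 1 by the F-test, the 1 being without concomitant tumour 3, where SLC2A5 passed in both its comparisons. Called lists then ranged from 3 (without vehicle tumour 2) to 11 (without vehicle tumour 3), from 7 to 12 and from 7 to 14. For sequential minus vehicle they were 11 without vehicle tumour 1, sequential tumour 2 or 3 and 12 without vehicle tumour 3 or sequential tumour 1. The cause was not tested. The correlation between schedules ranged from 0.321 to 0.601.

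Of 1780 alternative values of named genes, 1779 kept their side of the threshold, and the exception was SLC2A5. Those 1779 also moved by no more than the gene's residual SD between tumours. Omission of 1 of the 3 tumours in a group cannot move a difference beyond that limit. Several other alternatives leave the difference unchanged by construction, so for all of these the limit decides nothing. The sign turned for at most 2 of 35, 5 of 36 and 2 of 41 named genes, without concomitant tumour 2, vehicle tumour 3 and sequential tumour 2. Replicate numbers gave no sign of pairing the tumours. After each gene's group mean was removed, same-numbered tumours of different groups had correlations of -0.203 to 0.153, and 1 of 9 was over 0.1. Among the tumours of the other groups, 4 of 9 tumours correlated best with one of their own number. With the replicate block, 0 genes were called in every comparison and 9, 8 and 10 lists, so it ended no call. Precision is limited by 3 tumours per group, and for the 7074 dim genes by signal close to background.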

Other observations

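Comparisons with other splits of the tumours and the fits without 1 tumour were planned, whereas the tests with simulated data, of vehicle tumour 1 as a cause, of other stromal lists, of the spread of lists, and of the relation between ERK output and hypoxia lists were chosen after list results and levels had been seen. Proliferation genes varied more between tumours of the same group than between groups. The mitosis list had the largest SD within groups of all 56 lists, 0.418, ran from -0.56 in concomitant tumour 1 to 0.48 in concomitant tumour 3, and had 2.24% of its variance between groups. Replication-dependent histone genes, which resemble each other in sequence, had an SD of 0.336 and 2.97% between groups. The proliferation marker MKI67 was 11.16, 11.98 and 12.26 in the concomitant tumours and 11.28, 12.60 and 11.78 in the sequential tumours. The vehicle tumours lay closer together, at 12.04, 12.15 and 12.06. Over all lists the median share between groups was 28.0%, where 25% is expected with no effect.

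Complex I, AMPK and mTOR, RAF and receptor, and angiogenic factor lists did not pass against vehicle by limma's camera. ERK output genes differed by 0.25 on the concomitant schedule (adjusted p = 0.0680) and -0.20 on the sequential schedule, where they passed at the preset correlation (adjusted p = 0.00993) but not with an estimated correlation (adjusted p = 0.689). That call was lost without sequential tumour 2 (adjusted p = 0.460, mean -0.08), and without vehicle tumour 2 (adjusted p = 0.114) with the mean nearer its size, at -0.14. Respiratory complex I genes, subunits of the metformin-sensitive complex, differed by 0.04 on the concomitant schedule (adjusted p = 0.798) and 0.08 on the sequential schedule (adjusted p = 0.0891). AMPK and mTOR pathway genes differed by 0.06 (adjusted p = 0.486) and 0.03 (adjusted p = 0.701). Genes for RAF kinases and for VEGF and PDGF receptors differed by -0.08 (adjusted p = 0.239) and -0.04 (adjusted p = 0.435), and angiogenic factors by 0.00 (adjusted p = 0.898) and -0.10 (adjusted p = 0.320). Among the 3739 unnamed probe sets, limma called 0 in each comparison, with 191, 128 and 198 at an unadjusted p under 0.05 where chance gives 186.95.

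Fibroblast and matrix markers were lower than in vehicle tumours on both schedules by camera at the preset correlation, at means of -0.35 and -0.36, but did not pass with an estimated correlation (adjusted p = 0.848 and 0.689). Both calls rested on vehicle tumour 1, whose level was 0.58 against 0.20 and -0.07 in the other vehicle tumours, since without it the lower adjusted camera p was 0.171 and the means -0.17 and -0.19. The concomitant call was also lost without the dim genes (adjusted p = 0.546), and without concomitant tumour 1 (0.153) or 3 (0.104), but there the means stayed at -0.28 and -0.27, so no dependence on these tumours was shown. A loss of mouse stroma of every type was also considered. Over brighter members, endothelial, pericyte and macrophage markers pooled had a median difference of 0.015 (21 genes), and fibroblast markers had -0.16 (5 genes). The gap between these medians was within 2 standard errors, 0.762. That error treats genes as replicates and does not measure the spread between tumours. Nor does the pooled median describe each type. Over all members, pericyte markers were also highest in vehicle tumour 1, at 0.26, while endothelial and macrophage markers were highest in treated tumours. With so few bright members the test cannot decide, and this explanation stays open. An effect of treatment stays open and was not tested beyond this.

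The number of called lists was set against other groupings of the same tumours. Over the 3 comparisons 23 lists were called, and 84 of 100 splits of the 9 tumours gave as many (highest other 48), as did 72 of 100 data sets simulated with the tumours' gene-gene covariance and no group effect (highest 48), so variation shared by the genes of a list could give such counts. The simulated data held no independent noise per gene, so their counts are only an approximate guide. Chance could not be excluded for the 767 genes at an unadjusted p under 0.05 by the F-test, since 54 of 100 splits gave as many (highest other 1666). The F-test called 0 genes in the real groups, so all 100 splits must give as many and this count decides nothing (highest other 3). In pairs of groups the 10 splits are too few for a share under 0.05, and for the real counts of 0 genes their outcome is fixed. For concomitant minus vehicle, 10 splits gave at least 0 genes (highest other 1) and 8 at least 6 lists (highest other 19). For sequential minus vehicle, 10 gave at least 0 genes (highest other 0) and 9 at least 7 lists (highest other 16), and for sequential minus concomitant 10 gave at least 0 genes (highest other 1) and 5 at least 10 lists (highest other 19).

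By camera at the preset correlation, ERK output and hypoxia lists both lay lower on the sequential than on the concomitant schedule. Neither list passed with an estimated correlation. Their differences prompted the question whether the lists vary together between tumours of a group. After each group's mean was removed, Pearson's r over the 9 tumours was 0.417 (permutation p = 0.261) and Spearman's rho 0.483 (permutation p = 0.194), with an adjusted p of 0.261 for both by Benjamini-Hochberg over this 1 relation's pair of tests. The permutations ran over all 9 tumours regardless of group. Values centred within a group are not independent, so these p-values are approximate. Without the tumours farthest from the median ERK level, concomitant 1 and 2, r was 0.449. A shared source of variation between tumours was neither shown nor excluded with 9 tumours.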
